A study of Homo sapiens with 9 samples.

How the data were processed

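Transcript levels were measured in 9 samples of H9, an established line of human embryonic stem cells, all named day 3 in the labels. 3 samples received no siRNA, 3 a non-silencing siRNA and 3 an siRNA against TCF7L1, and each sample was hybridized to 1 array. Per the labels, total RNA was isolated with a column kit, turned into fragmented single-stranded DNA and labelled with biotin for Affymetrix whole-transcript arrays. The siRNA sequences, the dose and the way the siRNA was delivered are not given in the sources used here. Nothing in the labels says that the replicates were separate cultures, so every p-value given here measures only the spread between these samples.

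The deposited values are intensity signals on a linear scale, 1 for each probe set on each array. Per the submitters' processing notes they were made with Affymetrix Expression Console 1.1.1 and PLIER 2.0, which combines the probes of a probe set into 1 signal through a model of probe response. The background and normalization steps within that software are not given in the sources used here. The values of 2 deposited tables were compared and were equal, with a largest difference of 0. The gene symbols, the positions and the gene ontology terms came from the annotation deposited with the signals. Of 5950 probe sets whose transcript text gives a position on build 37 of the human genome, 97.5% overlapped that position, so positions are given on that build.

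The table held 33297 probe sets, of which 4201 were control probe sets and were left out of the tests. Signals were turned into log2 after 16 was added, which damps noise at low signals and understates the change of dim genes. A probe set was tested when its value lay above the 25th percentile of its own array on at least 3 arrays, which kept 22784 of 29096 probe sets and left out 6312 dim ones. A tested probe set held a median of 28 probes. A single gene symbol was given for 19490 of the tested probe sets, and 781 tested probe sets had the same 9 values as another tested probe set. Symbols were matched to a current gene table by accession (20232 probe sets), symbol (824) or synonym (504), and 451 were not matched. For lists, the probe set with the highest mean represented each gene, which gave 17913 genes. The chosen probe set annotated NANOG lies on chromosome 15, where a copy of the gene sits, and the other lies on chromosome 12.

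A linear model with 1 mean per group was fitted to the 9 arrays with limma 3.58.1 under R 4.3.3, with 6 residual and 4.89 prior degrees of freedom. The 3 comparisons were TCF7L1 siRNA against non-silencing siRNA, non-silencing siRNA against no siRNA, and TCF7L1 siRNA against no siRNA. Tests were two-sided, p-values were adjusted by the method of Benjamini and Hochberg within each comparison, and an adjusted p under 0.05 was the threshold. Differences are on the log2 scale with the standard error (SE) of the model, folds are taken on the same scale, and signals are means with the standard deviation (SD) of 3 samples. A probe set was counted as changed the same way against both controls when it passed in both comparisons with 1 sign, and the count was set against 100 simulated data sets without change. The array number sets the precision: the median SE of a difference was 0.119 and the median half-width of its 95% interval was 0.26. On simulated data of the same size with 200 changed probe sets, 60.7% of changes of 1.5-fold, 97.6% of changes of 2-fold and 99.8% of changes of 3-fold were recovered, with 89 false calls over 10 draws. The simulated noise was independent between probe sets, and the adjusted threshold is harder to reach when fewer probe sets change. These shares can therefore overstate recovery in the real data, where few probe sets passed.

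Genes were named by a rule: in the comparison of the 2 siRNAs up to 12 per direction, and in the other comparisons up to 6 per direction, those that passed by size of difference and then those of smallest p. TCF7L1, every list member that passed over all genes, and a fixed set of pluripotency, lineage, Nodal and Wnt genes were given by value. Genes that passed only over their list, and the 2 genes of smallest p in each list past the threshold, were added after their values were seen. The 23 lists were pluripotency, naive-state pluripotency, primitive streak and mesendoderm, definitive endoderm, mesoderm, neural ectoderm, neural crest, trophoblast and amnion, Wnt/beta-catenin targets, Nodal/TGF-beta targets, BMP targets, FGF/ERK targets, TCF/LEF family and cofactors, interferon response, p53 targets, cell cycle, cholesterol biosynthesis, unfolded protein and integrated stress response, hypoxia and glycolysis, epithelial and mesenchymal state, fibroblast markers, haematopoietic markers and small RNA machinery. The lists were tested with camera, a competitive test of limma, at a preset correlation of 0.01 between genes, with p-values adjusted over the 23 lists. On simulated data a list shifted by 0.3 was found in 10 of 10 draws and 0 other lists were called. The simulated genes were independent of each other, so this does not measure false calls of lists whose genes vary together. The shift was also larger than the median of every list that passed. The 1020 gene ontology terms of 10 to 300 genes were tested the same way after the data had been seen.

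The groups, the comparisons, the lists, the filter, the thresholds and the first set of alternatives were fixed before the data were examined. The alternatives were offsets of 1 and 64, quantile normalization, median centring, no filter, a filter at the array median, the values of the other deposited table, probe sets with 1 symbol alone, a fit of only the 2 groups compared, the replicate number as a block, a trended and robust variance, array weights, a minimum of 1.5-fold, each array left out in turn, and for the lists an estimated correlation and the rotation test fry. After the arrays had been seen, 4 more were added: the spread of each array as a covariate, array weights estimated gene by gene, the 2 arrays of narrowest spread left out, and the mean of both controls in place of the non-silencing siRNA. The replicate number was checked as a pairing and not used as one, since the deviations of same-numbered arrays correlated from -0.26 to 0.68 and only 5 of 9 arrays correlated best with an array of their own number. Array spread is the interquartile range of the log2 signals of an array. For each list, the median weight on the first principal component of the tested probe sets was placed among those of 10000 random lists matched on mean signal.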

Results

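TCF7L1 belongs to the TCF/LEF family of DNA-binding partners of beta-catenin and is known mostly as a repressor of Wnt target genes in pluripotent cells. Median signals of the 9 arrays lay between 104 and 113. The spread of the arrays was less even: the interquartile range was 3.16, 3.26 and 3.20 in the samples given no siRNA, 3.28, 3.08 and 2.95 with the non-silencing siRNA and 3.23, 2.95 and 3.10 with TCF7L1 siRNA. Arrays of the same group correlated at r = 0.979 to 0.993. Arrays of different groups correlated about as closely. Their r ran from 0.9765 (non-silencing replicate 1 with TCF7L1 replicate 2) to 0.996 (no siRNA replicate 2 with non-silencing replicate 1). The first principal component of the tested probe sets held 53.1% of the variance and followed this spread, with narrow and wide arrays in each siRNA group and all 3 arrays without siRNA on the wide side. Its relation to array spread was r = -0.981 over 9 arrays (exact permutation p = 6.34e-05; rho = -0.967, exact permutation p = 0.000165; r = -0.936 without the 2 arrays of most distant spread; adjusted p = 0.000127 over 2 relations).

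**Figure D1:**
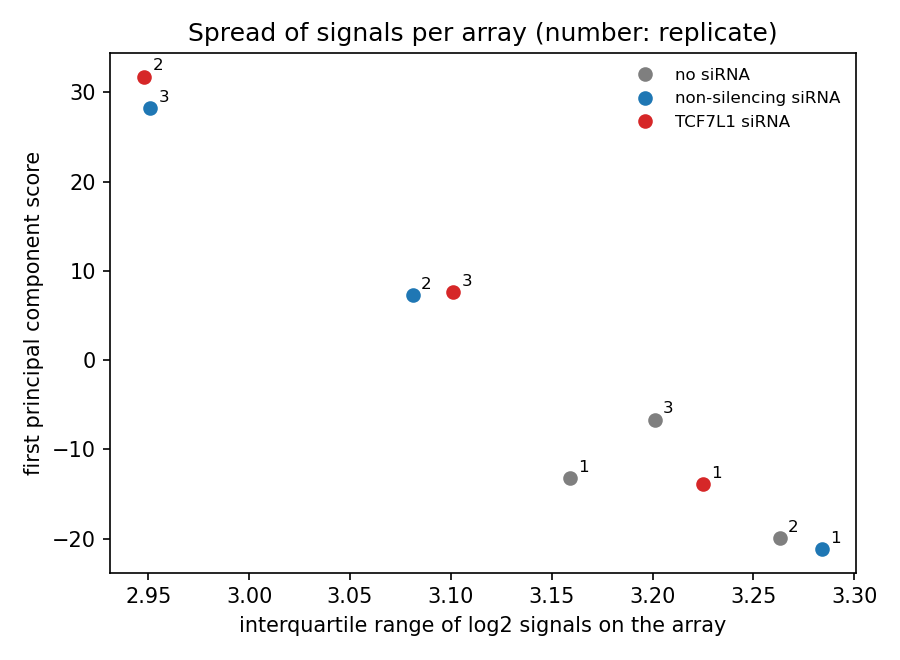
Score of each of the 9 arrays on the first principal component of the tested probe sets (vertical axis) against the interquartile range of its log2 signals (horizontal axis). Colours mark no siRNA, non-silencing siRNA and TCF7L1 siRNA, and numbers mark replicates.

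The siRNA against TCF7L1 removed most of its transcript. Signals of TCF7L1 were 1474, 1842 and 1667 in the samples given no siRNA, 1709, 1703 and 1625 with the non-silencing siRNA, and 389, 346 and 352 with TCF7L1 siRNA. The means were 1661 ± 184, 1679 ± 46.6 and 362 ± 23.2 (SD, n = 3 each), so that 21.6% of the signal with the non-silencing siRNA and 21.8% of that without siRNA remained. TCF7L1 fell by 2.17 on the log2 scale against the non-silencing siRNA (SE 0.10, adjusted p = 7.26e-06) and fell by 2.14 against no siRNA (SE 0.10, adjusted p = 8.05e-06). For the signals of TCF7L1 alone the exact permutation p was 0.1, the smallest that 3 samples against 3 can give. The probe set covers 85360583 to 85537505 on the plus strand of chromosome 2.

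Against the non-silencing siRNA, 5 genes rose and TCF7L1 was the only gene that fell past the threshold. DACT1, which encodes a Dishevelled-binding antagonist of Wnt signalling, rose from 180.1 ± 13.9 to 561 ± 44.3 (SD, n = 3), a log2 difference of 1.56 (SE 0.10, 2.94-fold, adjusted p = 9.6e-05). NODAL, the TGF-beta ligand that specifies mesendoderm, rose from a low signal of 33.3 ± 3.59 to 95.5 ± 0.201 (1.18, SE 0.09, 2.27-fold, adjusted p = 0.00061). The lower signals lay near the 25th percentile of their arrays, and over the alternatives the log2 difference of NODAL ran from 0.714 to 1.498. SMARCA2, an ATPase of the SWI/SNF chromatin remodelling complex, rose from 71.3 ± 6.02 to 174 ± 21.4 (1.12, SE 0.11, 2.17-fold, adjusted p = 0.00353). FST, the gene of the activin-binding protein follistatin, rose from 137 ± 19.4 to 326 ± 60.2 (1.16, SE 0.14, 2.23-fold, adjusted p = 0.0219). THBS2, the gene of the matrix protein thrombospondin 2, rose from 251 ± 11.3 to 509.8 ± 79 (0.97, SE 0.13, 1.96-fold, adjusted p = 0.0455). Each of the 5 genes was higher in all 3 samples given TCF7L1 siRNA than in any of the 6 other samples. Without siRNA the signals were 185 ± 12.5 for DACT1, 35.2 ± 3.61 for NODAL, 77.9 ± 7.2 for SMARCA2, 148 ± 14 for FST and 247 ± 34 for THBS2.

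The 5 genes lie on 5 chromosomes. DACT1 spans 59104859 to 59115039 on the plus strand of chromosome 14, NODAL 72192071 to 72201466 on the minus strand of chromosome 10, SMARCA2 2015342 to 2193624 on the plus strand of chromosome 9, FST 52776417 to 52781943 on the plus strand of chromosome 5, and THBS2 169615875 to 169654139 on the minus strand of chromosome 6. Among 22784 tested probe sets, 588 had an unadjusted p under 0.05 (280 higher and 308 lower), or 2.58% where chance gives 5%. The signals of the 2 groups did not overlap in 1138 probe sets, or 5% where chance gives 10%. FST missed the threshold when no siRNA replicate 1 or 3 (adjusted p = 0.081, 0.0572), non-silencing replicate 1 or 3 (0.0857, 0.124) or TCF7L1 replicate 1 or 3 (0.079, 0.085) was left out, and also with an offset of 1 (0.0559), in a fit of only the 2 groups (0.177) and without the 2 arrays of narrowest spread (0.0721). THBS2 missed it when any 1 of the 9 arrays was left out (no siRNA 0.0523, 0.109 and 0.076; non-silencing 0.131, 0.348 and 0.135; TCF7L1 0.0928, 0.0708 and 0.212, in replicate order), and also with an offset of 1 (0.111), quantile normalization (0.0643), no filter (0.055), a fit of only the 2 groups (0.177) and without the 2 arrays of narrowest spread (0.194). DACT1, NODAL, SMARCA2 and TCF7L1 remained past it each time 1 array was left out, but the filter at the array median left NODAL untested.

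**Figure D2:**
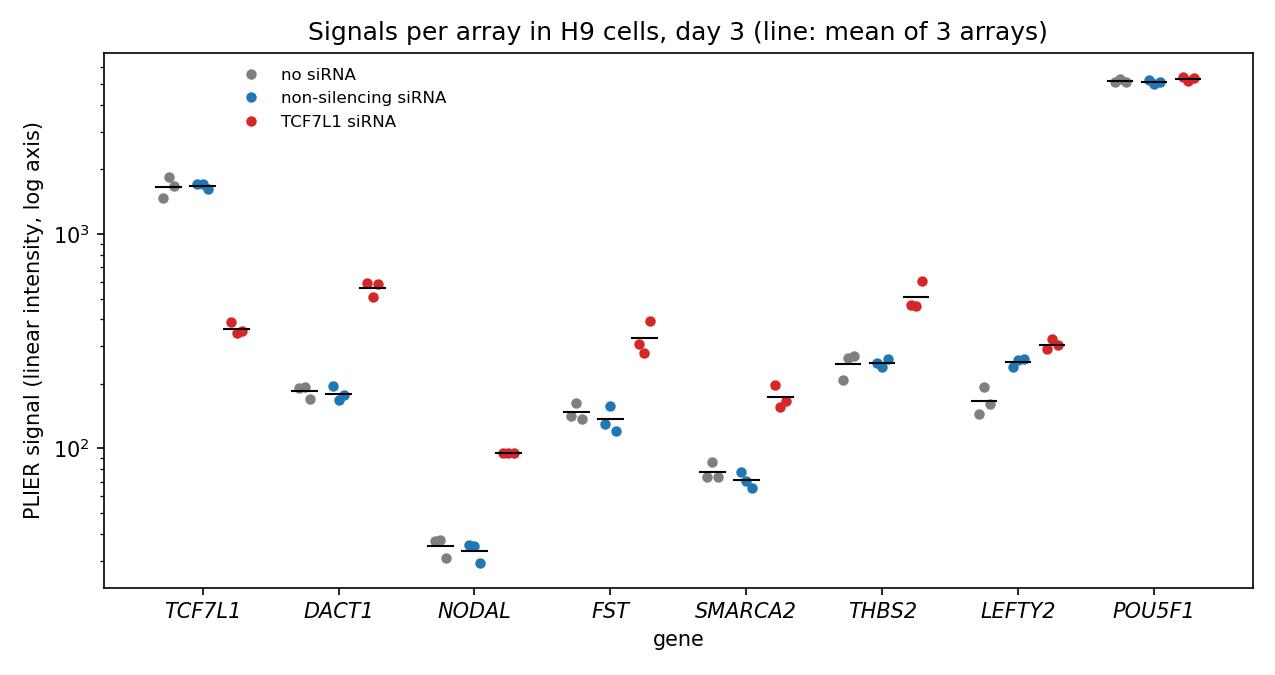
Signals of TCF7L1, DACT1, NODAL, FST, SMARCA2, THBS2, LEFTY2 and POU5F1 on each array (vertical log axis, intensity) in samples given no siRNA, non-silencing siRNA or TCF7L1 siRNA. Lines are the means of 3 samples.

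Other genes had sizeable differences without passing the threshold. FAT4, an atypical cadherin gene, had 193.6 ± 47.6 with TCF7L1 siRNA and 73.2 ± 8.14 with the non-silencing siRNA (log2 difference 1.21, SE 0.19, n = 3, adjusted p = 0.148), and the lysophosphatidic acid receptor gene LPAR6 had 126 ± 20.5 and 54.4 ± 17.1 (1.04, SE 0.18, adjusted p = 0.179). FAT4 passed in 6 of 25 alternatives and LPAR6 in 3 of 24. Smaller differences were those of HHLA1 (0.72), FLJ38379 (0.61), STOX2 (0.61) and the zinc transporter gene SLC39A8 (0.58), each at adjusted p = 0.155, and SALL3 (0.57, adjusted p = 0.179). On the lower side were FAM65B, now RIPOR2 (-0.95, adjusted p = 0.335), the galectin gene CLC (-0.91, 0.179), TMEM14A (-0.67, 0.179), AIF1 (-0.65, 0.155) and the diacylglycerol kinase gene DGKK (-0.59, 0.155). They were followed by TMEM59L (-0.57, 0.532), TMEM130 (-0.49, 0.285), ST8SIA5 (-0.48, 0.296), ANO1 (-0.48, 0.63), the collagen gene COL1A1 (-0.46, 0.296), STMN3 (-0.41, 0.471) and C16orf89 (-0.38, 0.633). The forkhead gene FOXB1, given by value, had 424 ± 63.6 and 304 ± 38.1 (0.45, SE 0.13, adjusted p = 1).

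The primitive streak and mesendoderm list and the Nodal/TGF-beta list, both of which hold NODAL, stood higher with TCF7L1 siRNA than with the non-silencing siRNA. Of 18 primitive streak genes 13 lay above 0 with a median of 0.04 (adjusted p = 0.000104 by camera; adjusted p = 0.32 with an estimated correlation). NODAL alone passed over all genes. Adjusted over the list alone, 3 genes passed, NODAL and the Wnt ligand genes WNT8A (0.39, SE 0.09, adjusted p = 0.0133) and WNT3 (0.29, SE 0.08, adjusted p = 0.0286). The streak regulators T, now TBXT (0.10, SE 0.13), MIXL1 (0.12, SE 0.10) and GSC (0.20, SE 0.14) did not pass, and EOMES had 193 ± 9.26 and 194 ± 24.6. Of 12 Nodal/TGF-beta targets 8 lay above 0 with a median of 0.14 (adjusted p = 0.000104; adjusted p = 0.235 with an estimated correlation), and only NODAL passed over all genes or adjusted over the list alone. With NODAL taken out of every list, the median of this list was 0.06 (adjusted p = 0.0245) and that of the primitive streak list 0.04 (adjusted p = 0.0132). The Nodal targets LEFTY1 (0.25, SE 0.12), LEFTY2 (0.25, SE 0.11) and PMEPA1 (0.26, SE 0.10) did not pass. The primitive streak list missed the threshold without non-silencing replicate 1 (0.275), without TCF7L1 replicate 2 (0.44) and with a filter at the array median (0.281). Among the genes that filter dropped were NODAL, WNT8A and MIXL1, whose signals lay below the median on every array. T, above the median on fewer than 3 arrays, was dropped too, so the filter tested a smaller list. The cause of the losses without 1 array was not tested. The Nodal/TGF-beta list kept its call without any 1 array (lowest 9.29e-05, highest 0.00865).

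Another 4 lists passed in this comparison, 3 of them higher. In the definitive endoderm list 12 of 13 genes lay above 0 (median 0.06, adjusted p = 0.00991; adjusted p = 0.32 with an estimated correlation), with EPHA4 at 0.33 (SE 0.12), FOXA2 at 0.35 (SE 0.17) and SOX17 at 0.07 (SE 0.18). In the BMP target list 8 of 13 genes lay above 0 (median 0.07, adjusted p = 0.0133; adjusted p = 0.235 with an estimated correlation), with ID1 at 0.30 (SE 0.14) and SMAD7 at 0.33 (SE 0.15). In the unfolded protein and integrated stress response list 12 of 15 genes lay above 0 (median 0.07, adjusted p = 0.0227; adjusted p = 0.706 with an estimated correlation), with DDIT3 at 0.28 (SE 0.16) and CEBPB at 0.12 (SE 0.11). No gene of these 3 lists passed over all genes or adjusted over the list alone by limma. The fibroblast list was lower, with 3 of 10 genes above 0 (median -0.11, adjusted p = 0.00991; adjusted p = 0.235 with an estimated correlation). COL1A1 (-0.46) passed adjusted over the list alone (adjusted p = 0.00338) and COL1A2 (-0.23, SE 0.11) did not. Without non-silencing replicate 1 the endoderm (0.539), BMP (0.401) and fibroblast (0.0736) lists missed the threshold, and without TCF7L1 replicate 2 the endoderm (0.172) and BMP (0.0798) lists. The BMP list missed it without TCF7L1 replicate 3 (0.103), and the stress list without non-silencing replicate 2 (0.155) or 3 (0.577) or TCF7L1 replicate 1 (0.774). Along the component that follows array spread, the primitive streak and BMP lists lay at percentiles 99.97 and 99.89 of random lists and the stress list at 1.9, while the endoderm (84.2), Nodal (91.7) and fibroblast (13.2) lists lay within the central 95%.

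**Figure D3:**
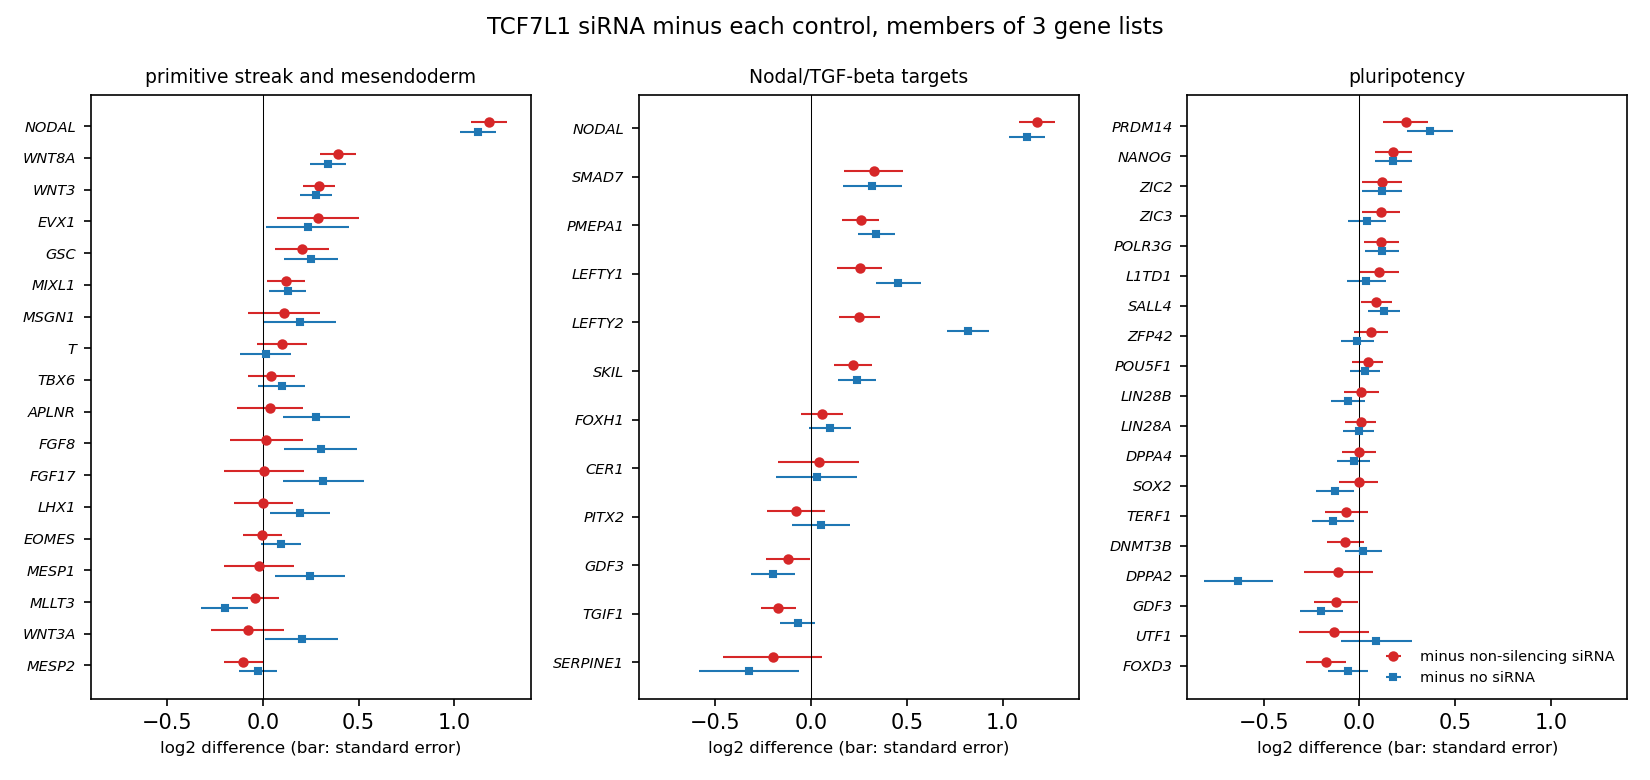
Log2 differences of the members of the primitive streak and mesendoderm, Nodal/TGF-beta and pluripotency lists with TCF7L1 siRNA minus non-silencing siRNA (red circles) and minus no siRNA (blue squares). Bars are standard errors, n = 3 per group.

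The core pluripotency factors stayed at high signals after TCF7L1 was reduced. POU5F1 had 5279 ± 113 with TCF7L1 siRNA and 5124 ± 117 with the non-silencing siRNA, and SOX2 2477 ± 266 and 2478 ± 140 (n = 3 each). NANOG had 2164 ± 201 and 1909 ± 72.9 on the probe set of chromosome 15 and 2095 ± 212 and 1844 ± 79 on that of chromosome 12, a difference of 0.18 on each. In the pluripotency list (19 genes, median 0.01, adjusted p = 0.186) no gene passed by limma over all genes or over the list alone. In the naive-state list (10 genes, adjusted p = 0.186) the nuclear receptor gene NR5A2 (0.66, SE 0.13, adjusted p = 0.00303) and KLF5 (0.32, SE 0.11, adjusted p = 0.0422) were higher and DPPA3 (-0.43, SE 0.14, adjusted p = 0.0422) lower when adjusted over the list alone. BMP4 passed over the mesoderm list alone (0.58, SE 0.11, adjusted p = 0.00315; list 0.0723), and ETS1 over the neural crest list alone (0.35, SE 0.10, adjusted p = 0.0443; list 0.883).

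Canonical Wnt targets, which TCF7L1 is known to repress, had small differences. AXIN2 had 0.16 (SE 0.10), LEF1 0.15 (SE 0.13), SP5 0.08 (SE 0.12) and TCF7 0.05 (SE 0.09), and the Wnt/beta-catenin list did not pass (19 genes, 14 above 0, adjusted p = 0.186). TCF7L2, the paralogue expressed at 919 ± 89.6, had 0.07 (SE 0.11), and the TCF/LEF family list stood at adjusted p = 0.587. The other lists were neural ectoderm (0.419), trophoblast and amnion (0.804), FGF/ERK targets (0.316), interferon response (0.202), p53 targets (0.0562), cell cycle (0.0562), cholesterol biosynthesis (0.95), hypoxia and glycolysis (0.667), epithelial and mesenchymal state (0.635), haematopoietic markers (0.95) and small RNA machinery (0.755). The hypoxia, epithelial and mesenchymal, small RNA and haematopoietic lists had a median or mean below 0 while the test pointed upward.

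The non-silencing siRNA changed no single gene past the threshold against no siRNA. LEFTY2, an antagonist of Nodal signalling, had the smallest p: 254 ± 11.3 against 167 ± 25.1 (log2 difference 0.57, SE 0.11, n = 3, adjusted p = 0.927). It passed adjusted over the Nodal/TGF-beta list alone (adjusted p = 0.00346). Next on the higher side were KRTAP9-3 (0.69), RNF185 (0.55), SLC37A2 (0.43), UBE2K (0.39) and RAB40AL (0.34). On the lower side were the lysosomal lipase gene LIPA (-0.43), KLHL24 (-0.42), SV2B (-0.41), KLKB1 (-0.41), OBFC2A, now NABP1 (-0.36) and KCNJ2 (-0.30). All of these stood at adjusted p = 0.927. Limma called 0 probe sets, with 548 at an unadjusted p under 0.05 (264 higher and 284 lower, or 2.41% where chance gives 5%). In all, 1563 probe sets had groups that did not overlap (6.9% where chance gives 10%). TCF7L1, NODAL and DACT1 had 1679, 33.3 and 180.1 with the non-silencing siRNA and 1661, 35.2 and 185 without.

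p53 targets and cholesterol biosynthesis genes as groups were lower with the non-silencing siRNA than without siRNA. Of 20 p53 targets 2 lay above 0 (median -0.10, adjusted p = 0.00903; adjusted p = 0.9 with an estimated correlation), with CDKN1A at -0.40 (SE 0.12) and RRM2B at -0.31 (SE 0.11). Of 19 cholesterol biosynthesis genes 1 lay above 0 (median -0.12, adjusted p = 0.00809; adjusted p = 0.9 with an estimated correlation), with STARD4 at -0.27 (SE 0.10) and IDI1 at -0.20 (SE 0.10). Wnt/beta-catenin targets were higher, 14 of 19 above 0 (median 0.07, adjusted p = 0.0129; adjusted p = 0.338 with an estimated correlation), with SP5 at 0.25 (SE 0.12) and NKD2 at 0.20 (SE 0.10). No gene of these 3 lists passed over all genes or adjusted over the list alone by limma. Along the component that follows array spread the Wnt list lay at percentile 98.3 of random lists, the p53 list at 3.68 and the cholesterol list at 0. With array spread as a covariate the Wnt (0.101), p53 (0.12) and cholesterol (0.0705) lists missed the threshold. So did the Wnt list without no siRNA replicate 1 (0.0751) or non-silencing replicate 3 (0.0656), the p53 list without non-silencing replicate 3 (0.0656) and the cholesterol list without no siRNA replicate 1 (0.123). In turn 8 lists passed without no siRNA replicate 3 and 10 without non-silencing replicate 1.

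The remaining lists did not pass between the 2 controls. Nearest to the threshold were primitive streak and mesendoderm, trophoblast and amnion, and Nodal/TGF-beta targets (adjusted p = 0.0782 each), followed by neural ectoderm (0.0942), haematopoietic markers (0.113), definitive endoderm and the unfolded protein and integrated stress response (0.225 each) and mesoderm (0.297). BMP targets, FGF/ERK targets and hypoxia and glycolysis stood at 0.618, epithelial and mesenchymal state at 0.717 and neural crest at 0.914. The interferon response list had a median of 0.006 over 22 genes (adjusted p = 0.988), and its members IFIT2, IFIT3, IFI44, OAS3 and RSAD2 were not tested. Pluripotency, naive-state pluripotency, TCF/LEF family, cell cycle, fibroblast markers and small RNA machinery also stood at 0.988. Median, mean and test differed in sign for the interferon, naive-state, TCF/LEF and fibroblast lists.

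Against no siRNA, the same 5 genes rose together with LEFTY2 and STOX2, and CLC, AIF1 and TCF7L1 fell. DACT1 rose by 1.52 on the log2 scale (SE 0.10, 2.87-fold, adjusted p = 0.000123), NODAL by 1.13 (SE 0.09, 2.18-fold, 0.000983), FST by 1.05 (SE 0.14, 2.07-fold, 0.0303), SMARCA2 by 1.01 (SE 0.11, 2.02-fold, 0.00933) and THBS2 by 0.998 (SE 0.13, 0.0303), n = 3 per group. LEFTY2 rose from 167 ± 25.1 to 305 ± 16 (0.82, SE 0.11, 1.77-fold, adjusted p = 0.0303) with the non-silencing siRNA in between at 254 ± 11.3, and the storkhead-box gene STOX2 from 175 ± 16 to 306 ± 21.7 (adjusted p = 0.0303). CLC, a galectin of eosinophils, fell from 131 ± 23.4 to 44.1 ± 4.62 (-1.28, SE 0.16, adjusted p = 0.0303), and AIF1, a calcium-binding protein of macrophages, from 249.5 ± 13.7 to 138 ± 2.26 (-0.79, SE 0.11, adjusted p = 0.0321). AIF1 is held by 3 probe sets with equal values, so that 12 probe sets stand for 10 genes. LEFTY2 spans 226124298 to 226129189 on the minus strand of chromosome 1, STOX2 184826509 to 184938875 on the plus strand of chromosome 4, CLC 40221895 to 40228668 on the minus strand of chromosome 19 and AIF1 31583005 to 31584802 on the plus strand of chromosome 6. FAM65B (-1.29, SE 0.19, adjusted p = 0.0551), the potassium channel gene KCNJ2 (-0.54, SE 0.08, 0.0753), the chemerin receptor gene CMKLR1 (-0.87, SE 0.14, 0.115) and DGKK (-0.58, SE 0.10, 0.115) did not pass. FAM65B, with a difference as large as that of CLC, passed in 13 of 24 alternatives (adjusted p from 0.00018 to 0.414). At an unadjusted p under 0.05 there were 1653 probe sets (585 higher and 1068 lower, 7.26% where chance gives 5%), and 3271 had groups that did not overlap (14.4% where chance gives 10%). The count of 12 probe sets became 3 without no siRNA replicate 1, no siRNA replicate 3 or TCF7L1 replicate 3, 5 without non-silencing replicate 2, TCF7L1 replicate 1 or TCF7L1 replicate 2, and 6 without no siRNA replicate 2, with DACT1, NODAL and TCF7L1 past the threshold each time.

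Mesendoderm and signalling lists stood higher against no siRNA. Of 18 primitive streak genes 16 lay above 0 (median 0.22, adjusted p = 3.15e-06; adjusted p = 0.202 with an estimated correlation). NODAL passed over all genes, and WNT3 (0.28, SE 0.08, adjusted p = 0.038) and WNT8A (0.34, SE 0.09, adjusted p = 0.0348) besides it adjusted over the list alone. Of 12 Nodal/TGF-beta targets 9 lay above 0 (median 0.17, adjusted p = 2.11e-05; adjusted p = 0.19 with an estimated correlation). NODAL and LEFTY2 were past the threshold over all genes. Adjusted over the list alone 4 genes were, with LEFTY1 (0.46, SE 0.12, adjusted p = 0.0108) and PMEPA1 (0.34, SE 0.10, adjusted p = 0.0153) besides. Of 19 Wnt/beta-catenin targets 16 lay above 0 (median 0.15, adjusted p = 0.00214; adjusted p = 0.179 with an estimated correlation), with SP5 at 0.33 (SE 0.12) and AXIN2 at 0.23 (SE 0.10). The Wnt/beta-catenin list had not passed against the non-silencing siRNA (median 0.05, adjusted p = 0.186), and had passed between the 2 controls (median 0.07, adjusted p = 0.0129). Of 13 definitive endoderm genes 11 lay above 0 (median 0.15, adjusted p = 0.00315; adjusted p = 0.249 with an estimated correlation), with FOXA2 at 0.60 (SE 0.17) and EPHA4 at 0.28 (SE 0.12). These 4 lists kept their calls when any 1 array was left out, with highest adjusted p-values of 0.00263, 0.00142, 0.0118 and 0.0192. All 3 arrays without siRNA were of wide spread, so this comparison runs partly along array spread, and the primitive streak and mesendoderm (99.97) and Wnt (98.3) lists lay outside the central 95% of random lists along that component. With array spread as a covariate the adjusted p rose to 0.021 for the primitive streak and mesendoderm list, 0.021 for the Wnt/beta-catenin targets and 0.0384 for the definitive endoderm list.

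A second set of 4 lists passed against no siRNA with less margin. In the mesoderm list 13 of 15 genes lay above 0 (median 0.15, adjusted p = 0.0118; adjusted p = 0.619 with an estimated correlation), with BMP4 at 0.43 (SE 0.11) past the threshold adjusted over the list alone (adjusted p = 0.0285) and TEK at -0.32 (SE 0.11) against the direction of its list. In the BMP target list 10 of 13 genes lay above 0 (median 0.13, adjusted p = 0.0124; adjusted p = 0.19 with an estimated correlation), with SMAD7 at 0.32 (SE 0.15) and MSX2 at 0.25 (SE 0.13). In the neural ectoderm list 12 of 16 genes lay above 0 (median 0.09, adjusted p = 0.0398; adjusted p = 0.676 with an estimated correlation), with OTX2 higher (0.50, SE 0.12, adjusted p = 0.0227) and POU3F1 lower (-0.53, SE 0.15, adjusted p = 0.0406) adjusted over the list alone. Cholesterol biosynthesis was lower, 2 of 19 genes above 0 (median -0.14, adjusted p = 0.0118; adjusted p = 0.676 with an estimated correlation), with STARD4 at -0.26 (SE 0.10) and INSIG1 at -0.23 (SE 0.11). Without no siRNA replicate 1 the BMP (0.0852), cholesterol (0.137) and neural ectoderm (0.287) lists missed the threshold. Without no siRNA replicate 2 it was the mesoderm (0.0578) and neural ectoderm (0.0507) lists, and without TCF7L1 replicate 2 the mesoderm (0.206) and neural ectoderm (0.258) lists. It was the BMP (0.0712), cholesterol (0.0712) and neural ectoderm (0.154) lists without TCF7L1 replicate 3. The number of lists past the threshold was 5 without no siRNA replicate 1 or TCF7L1 replicate 3. With array spread as a covariate the mesoderm (0.577), neural ectoderm (0.807) and cholesterol (0.115) lists missed it as well, and the BMP targets stood at 0.0497. Along the component that follows array spread the mesoderm, neural ectoderm, cholesterol and BMP lists lay at percentiles 99.0, 99.5, 0 and 99.89 of random lists.

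Naive-state genes differed in both directions against no siRNA, and no gene of that list passed over all genes. Adjusted over that list alone, KLF4 (0.27, SE 0.10, adjusted p = 0.0406), KLF5 (0.30, SE 0.11, adjusted p = 0.0344) and NR5A2 (0.49, SE 0.13, adjusted p = 0.0189) were higher. TFCP2L1 (-0.41, SE 0.14, adjusted p = 0.0317), DPPA3 (-0.52, SE 0.14, adjusted p = 0.0189) and TFAP2C (-0.50, SE 0.16, adjusted p = 0.0317) were lower. Of these genes, KLF5, NR5A2 and DPPA3 also passed over the list alone against the non-silencing siRNA, while KLF4, TFCP2L1 and TFAP2C did not. The naive-state list did not pass (0.246). Of 16 FGF/ERK targets 9 lay above 0 (median 0.003) and the list did not pass (0.292). Adjusted over that list alone 3 of them were lower: SPRY4 (-0.39, SE 0.09, adjusted p = 0.0179), ETV5 (-0.60, SE 0.15, adjusted p = 0.0192) and SPRY2 (-0.33, SE 0.09, adjusted p = 0.0227). SNAI2 (-0.65, SE 0.15) was lower adjusted over the neural crest list alone (adjusted p = 0.011; list 0.757) and over the epithelial and mesenchymal list alone (adjusted p = 0.00877; list 0.985), in which ZEB2 was higher (0.40, SE 0.10, adjusted p = 0.00877). COL1A1 (-0.43, SE 0.09) was lower over the fibroblast list alone (adjusted p = 0.00537; list 0.0866). The haematopoietic list, of other markers than CLC and AIF1, stood at 0.177. The last lists were pluripotency (0.431), trophoblast and amnion (0.217), TCF/LEF family (0.697), interferon response (0.431), p53 targets (0.344), cell cycle (0.129), unfolded protein and integrated stress response (0.726), hypoxia and glycolysis (0.877) and small RNA machinery (0.88). Median, mean and test differed in sign for the pluripotency, neural crest, FGF/ERK, TCF/LEF, stress, epithelial and mesenchymal, and small RNA lists.

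DACT1, NODAL, FST, SMARCA2 and THBS2 rose and TCF7L1 fell against both controls. They were the 6 probe sets changed the same way in both comparisons, and TCF7L1 among them is the target of the siRNA. In 100 simulated data sets without change the mean was 0 and the highest value 0. Independent noise without change gives almost no calls in either comparison, so this value was nearly fixed in advance. It does not measure what the structure of the real arrays can give. Both comparisons use the same 3 TCF7L1 arrays, as did the simulated data, which hold no real change. Lists drawn independently would have 0.00154 higher and 0.000219 lower probe sets in common, and part of the excess over these values can come from the shared arrays. For genes that passed against no siRNA alone, the difference between the 2 comparisons is that between the controls: LEFTY2 0.57 (SE 0.11), STOX2 0.15 (SE 0.10), CLC -0.37 (SE 0.16) and AIF1 -0.14 (SE 0.11). None of these passed by limma, where the smallest adjusted p of any probe set was 0.927. The count was 3 without no siRNA replicate 1, no siRNA replicate 3 or TCF7L1 replicate 3, and DACT1, NODAL and TCF7L1 were past the threshold in both comparisons each time. Over all tested probe sets, 67.5% had the same sign in both comparisons and 66.7% in simulated data.

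**Figure D4:**
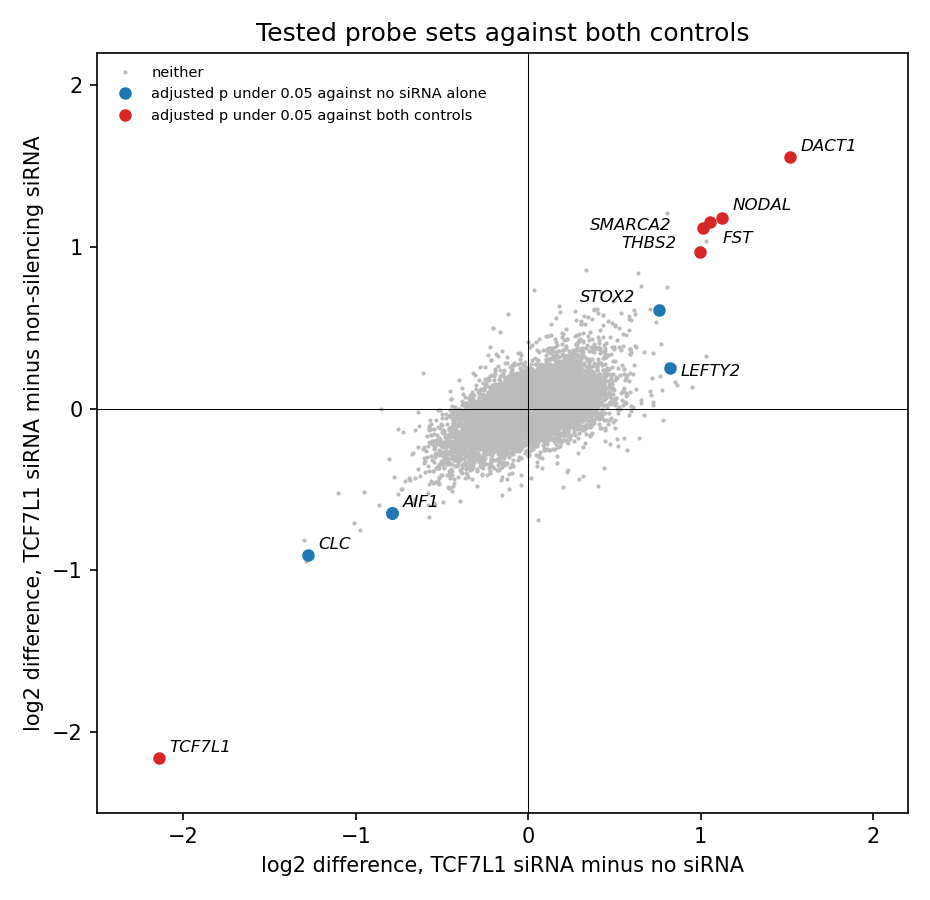
Log2 difference of each tested probe set with TCF7L1 siRNA minus non-silencing siRNA (vertical axis) against TCF7L1 siRNA minus no siRNA (horizontal axis). Red marks probe sets past the threshold in both comparisons and blue those past it against no siRNA alone.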

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

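Of the results of alternatives run for named genes, 2605 kept their sign and their side of the threshold, whether or not their size moved. A further 101 gained a call, 71 lost one and 16 changed sign. All 16 changes of sign were between the 2 siRNAs. Only for that comparison was the fixed set of genes given by value rerun whatever their p, so it does not stand out by this. SOX2, at -0.005, became 0.011 with quantile normalization, 0.063 with array weights, 0.003 with array spread as a covariate, 0.122 with weights gene by gene and 0.076 without the 2 narrowest arrays, and ranged from -0.063 to 0.086 without 1 array. EOMES, at -0.002, became 0.083 with array weights, 0.007 without the 2 narrowest arrays and 0.046 against the mean of both controls, and ranged from -0.1 to 0.066. SOX17, at 0.069, became -0.011 with weights gene by gene and ranged from -0.135 to 0.242. Without 1 array the count between the 2 siRNAs (6) ranged from 4 to 6, that between the controls (0, limma, 548 unadjusted) from 0 to 0, that against no siRNA (12) from 3 to 14 and that against both controls (6) from 3 to 5. Between the 2 siRNAs and against no siRNA the counts were 11 and 20 with the replicate number as a block. Against no siRNA it was 19 with a trended and robust variance and 2186 with array weights, whose default estimate was 24.7 for TCF7L1 replicate 3 and 0.000158 for non-silencing replicate 2. Chosen after the data were seen, array spread as a covariate gave 25 and 24 (13 against both), weights gene by gene 267 and 72 (53 against both), the 2 narrowest arrays left out 5 against no siRNA, and the mean of both controls 12. The lists past the threshold (6, 3 and 8) ranged without 1 array from 4 to 9, 2 to 10 and 5 to 9, and were 0, 0 and 0 with an estimated correlation (3, 1 and 4 unadjusted) and 0, 0 and 3 with fry (2, 1 and 4 unadjusted). Between the controls they were 5 with an offset of 64, 5 with a filter at the array median, 1 with array spread as a covariate and 1 without the 2 narrowest arrays. The cause was not tested.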

Other observations

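Gene ontology terms, tested after the data had been seen, gave few terms between the 2 siRNAs and more against no siRNA. Of 1020 terms, embryonic cranial skeleton morphogenesis was higher with TCF7L1 siRNA than with the non-silencing siRNA (12 genes, median 0.05, adjusted p = 0.0245). Sensory perception of smell, 160 genes that are mostly olfactory receptors, was higher with the non-silencing siRNA (median 0.10, adjusted p = 4.18e-07) and with TCF7L1 siRNA (median 0.12, adjusted p = 3.53e-07) than without siRNA. Keratinization was higher in the same 2 comparisons (34 genes, medians 0.16 and 0.19, adjusted p = 0.000211 and 0.000606) and cell division lower (249 genes, medians -0.07 and -0.10, adjusted p = 0.00803 and 0.00752). With an estimated correlation camera called 0 terms in any comparison (17, 8 and 27 at an unadjusted p under 0.05). Along the component that follows array spread, smell, keratinization and cell division lay at percentiles 100, 100 and 0.05 of random lists.

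The tests in this part were chosen after the result was seen, except the count of lineage lists along the first component. Arrays of narrow and of wide spread stood within each siRNA group, the 3 arrays without siRNA were all wide, and the first component of the tested probe sets followed that spread. The first component of the control probe sets followed the same order of arrays (r = 0.954, n = 9, exact permutation p = 0.000135, rho = 0.933, exact permutation p = 0.00075). Without the 2 most distant arrays r was 0.818, and the exact permutation p adjusted over 2 relations was 0.000135. These probe sets were taken as controls because the annotation gives them no chromosome and no accession, and what they read was not examined. Compression of the signals on some arrays is a candidate explanation, but this relation cannot tell it from differences in the RNA. Different lineage state of the cultures could also be involved. Along the first component of the tested probe sets, 4 of the 8 lineage and pluripotency lists lay outside the central 95% of random lists. These were primitive streak, mesoderm, neural ectoderm and neural crest. Of the lists that are not of lineages, the BMP (99.89), Wnt (98.3), cholesterol (0) and stress (1.9) lists lay outside as well, and the others of the 23 lay within. The count is therefore not particular to lineage lists. The genes of the random lists were drawn independently, so a list whose genes vary together can fall outside more easily. Neither explanation excludes the other, and both stay open.

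For the primitive streak list the tests without NODAL and with array spread as a covariate were chosen after the result was seen, as was the reading of the estimated correlation as a test of this pattern, while the estimated correlation itself, fry and leaving out 1 array had been fixed beforehand. That list stood higher with TCF7L1 siRNA than with the non-silencing siRNA and holds NODAL, which alone passed over all genes. With NODAL taken out of this list alone it still passed (adjusted p = 0.00991), which argues against NODAL as the whole cause. With array spread as a covariate it passed too (0.00438). The 2 siRNA groups had similar spread, so the covariate could hardly have ended the call and does not decide on spread. The call ended without non-silencing replicate 1 (0.275), the array of widest spread, or TCF7L1 replicate 2 (0.44), the narrowest. Along the component that follows spread the list lay at percentile 99.97 of random lists, so a part of array spread stays open. Over all alternatives run the adjusted p of the list ranged from 1.56e-07 to 0.515. Correlation among the genes of the list may account for the call, since with an estimated correlation the adjusted p was 0.32, and this stays open.

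The tests of the 5 genes that rose were all chosen after the result was seen. With array spread as a covariate 5 of the 5 genes DACT1, NODAL, FST, SMARCA2 and THBS2 passed. The 2 siRNA groups had similar spread, and the differences hardly moved (DACT1 1.557 without and 1.564 with the covariate, NODAL 1.18 and 1.184). The fit therefore speaks only against a linear trend with spread, which groups of similar spread could hardly show. RNA of fibroblasts in the samples given TCF7L1 siRNA would raise fibroblast genes, but the list (10 genes, 5 above the array median in cells given no siRNA and 0 held by another list) had a median of -0.113 (interquartile range 0.235), with COL1A1 at 307 and 427, COL1A2 at 344 and 407, THY1 at 1946 and 2162, and TAGLN the other way at 319.6 and 251 with TCF7L1 siRNA and with the non-silencing siRNA. The list members LUM and DCN were not tested, and COL1A1 read 430, 405 and 422 without siRNA. A small share of fibroblast RNA could therefore be missed. The list values argue against such RNA as the cause of all 5 rises only under a bound for the list median of 0.5. That bound was set by choice and not taken from a fibroblast profile. An effect of the siRNA on other transcripts than TCF7L1 stays open and was not tested, as no other siRNA against TCF7L1 was analysed here.

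The counts over other splits of the samples were planned. Of the 10 splits of the 6 samples given an siRNA, 2 gave as many probe sets as the real one (real 6, highest other 362); for no siRNA and non-silencing siRNA 10 of 10 did (real 0, highest other 0) and for no siRNA and TCF7L1 siRNA 1 of 10 (real 12, highest other 0), and 10 splits are too few for a share under 0.05. The split with 362 set non-silencing replicate 1 and TCF7L1 replicates 1 and 3 against the remaining 3 arrays, which include the 2 of narrowest spread, and so points to a structure of the samples. For probe sets changed the same way against both controls, 3 of 100 splits of the 9 arrays gave as many as the real one (real 6, highest other 312). That share lies under the planned bound of 0.05. The 100 splits are only a random part of all possible ones, and a wrong split gave far more than the real count. Chance is therefore not excluded. The split with 312 grouped TCF7L1 replicate 2 with non-silencing replicates 2 and 3, which again points to array spread as a structure of the samples, and the other kept the 3 TCF7L1 arrays together.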
